A study of Mus musculus with 4 samples.

How the data were processed

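The data were FPKM values (fragments scaled by transcript length and library size) of total RNA from brain, for 4 groups of mice with 1 library each. Per the labels' protocols, RNA from the left hemispheres of 5 mice per group was pooled and extracted with a lipid tissue kit, and libraries were made with a strand-specific kit; the series design speaks of whole brain instead. The authors deposited FPKM per transcript in 1 table per library, with gene, locus and length. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic 0.36, HISAT2, Cuffdiff and Cufflinks 2.2.1 were used and the build was mm9. The coordinates in the tables are those of GRCm38: 128066 of 128603 transcripts (99.6%) were found in the GENCODE M21 annotation, and 97.2% of these had the same start and end. Coordinates are therefore given in GRCm38. Whether reads were counted by strand, how reads with several matches were treated, and whether a CAST genome was used are not given in the sources used here. The tables hold no confidence intervals and no quantification status.

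Total FPKM was 2357188 in B6, 1857428 in CAST, 2347990 in F1i and 1942710 in F1r. The tables give no read counts, but low values of long transcripts sit at the worth of 1 fragment, and comparing transcripts at that step in both libraries gave a depth relative to B6 of 0.714 in CAST (36 transcripts), 0.807 in F1i (52) and 0.726 in F1r (48). The absolute depth is unknown, so no interval or detection limit is given. Transcripts at 0 made up 46.0% in B6, 48.5% in CAST, 48.0% in F1i and 48.1% in F1r.

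Transcripts under 200 bases and small RNA names were left out, because FPKM of fragments this short is dominated by its length correction, and the remaining transcripts were summed per gene. This gave 45184 genes, of which 13750 had a mean FPKM of at least 1 over the 4 libraries and entered the comparisons. Differences were computed as log2(FPKM + 1) of CAST minus B6, of F1r minus F1i, and of the mean of both F1 libraries minus the mean of both parents. With 1 library per group no test was run, and genes at least 2-fold apart on this scale were counted. The position of an F1 library between the parents was (F1 - B6)/(CAST - B6) on FPKM, and slopes of the reciprocal on the parental difference were least-squares fits across genes. Each of 37 gene lists of cell types, brain regions, receptors, pathways and imprinted genes is described by its median and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins; a list was called outside when it lay beyond the central 95%. The percentiles describe these libraries and are not p-values.

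The grouping, the comparisons, the 37 lists, most alternative settings and the rule for named genes were chosen before the data were examined. The rule took the 12 largest differences in each direction between CAST and B6 and the 8 largest for the other comparisons, members of a list at least 2-fold apart, the sex and strain check genes, and up to 4 members of a list described; names of the form Gm plus digits, names ending in Rik and accessions were passed over. Some genes that the rule names are not reported here. The 7 genes outside the parental range, the family members set beside a named gene, and the added selection of 15 protein-coding genes per side that share under 5% of their sequence were named after their values were seen, the last because reads of near-identical genes cannot be told apart. For that, every 31-base word of each gene's transcripts in GENCODE M21 was searched in the transcripts of all other genes, and the percent found is given as shared. Gene types came from the same annotation.

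Alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-ratio scaling, rescaling to a common total, single transcripts, positions on the log2 scale, and a 2-fold rule combined with the 99th percentile of the F1r against F1i difference. Protein-coding genes alone, genes with under 5% shared words, and list medians after rescaling less the median of all genes were added after the data were seen. An alternative rule based on confidence intervals was not run, as the tables have none. All steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated data for CAST against B6 and the F1 libraries over 13750 genes. Of genes planted with a log2 change of 1.5, 96.0% were called in the right direction, and 100% of those with 3. No unchanged gene was called, and the median F1i position of changed autosomal genes was 0.506. The slope over 40 changed X-linked genes was -1.003, and 3% of 100 unmoved lists lay outside the central 95%. The simulation gave each library independent noise with a standard deviation of 0.1 on the log2 scale. In the data, the F1r minus F1i difference had a standard deviation of 0.27, and 23 of 37 lists lay outside the central 95%. The simulated rates therefore do not carry over to these libraries.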

Results

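RNA abundance was measured in the brains of 2 inbred mouse strains and of the F1 hybrids from both directions of their cross. The strains were C57BL/6 (B6), a standard laboratory mouse, and CAST/EiJ (CAST), derived from wild Mus musculus castaneus. The hybrids were written in the labels as C57BL/6 x CAST/EiJ (F1i) and CAST/EiJ x C57BL/6 (F1r), with no statement of which parent was the dam. Each of the 4 groups was 1 library of RNA pooled from the left hemispheres of 5 mice, so no difference given here has a replicate check, an error or a p-value. Unless stated otherwise, differences are log2 ratios of FPKM + 1, which understate the change of low genes. A gene was counted as higher or lower when it was at least 2-fold apart. Relative to B6, the estimated sequencing depth was 0.714 in CAST, 0.807 in F1i and 0.726 in F1r. The Y-linked gene Ddx3y was at 17.5 FPKM in B6, 19.1 in CAST, 16.1 in F1i and 17.6 in F1r, whereas Xist, the RNA that silences an X chromosome in females, was listed at 0 in CAST and at no more than 0.0021 FPKM in the other libraries. Gabra2, a GABA-A receptor subunit known to be under-expressed in B6, was at 8.20 FPKM in B6, 27.3 in CAST, 18.0 in F1i and 20.4 in F1r. Nnt, the mitochondrial transhydrogenase that carries a deletion in the C57BL/6J substrain, was at 4.002, 7.99, 8.31 and 5.25 FPKM in the same order.

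The comparison of CAST with B6 asked how brain expression differs between the parental strains. The lists of myelin, microglial and antigen-presentation genes had medians below 0 in CAST, with 4 of 15, 0 of 15 and 6 of 13 members lower by the 2-fold rule. The glutamate receptor median was slightly above 0, with 0 of 21 members past the rule, and no pan-neuronal, excitatory or inhibitory neuron marker passed it. Of the 13750 genes compared, 390 were higher and 310 lower in CAST. The direction depended on gene type, with 133 higher and 225 lower among 12300 protein-coding genes, and 195 higher and 18 lower among 644 processed pseudogenes, the intronless copies of other genes. Every library was also rescaled to the same total over all transcripts, including those under 200 bases. Among the 11965 genes that then passed the filter, 368 were higher and 100 lower, and the median of all genes moved to 0.32. Values also became smaller, so the filter and the added 1 weighed more.

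Oligodendrocyte and myelin genes had a median log2 difference of -0.72, below all 10000 random lists matched on mean expression. Every one of the 15 measured members was lower in value, and 4 passed the 2-fold rule. These were Mobp (280 FPKM in B6 and 102 in CAST), Mal (85.3 and 37.2), Cldn11 (101 and 45.5) and Opalin (5.93 and 1.22), all of them components of the myelin sheath or its cells. Mbp, the major myelin basic protein, went from 1039 to 732 FPKM without passing the rule. Among 10 oligodendrocyte precursor genes, Sox10 (8.70 and 3.71 FPKM) and Bcas1 (49.1 and 23.9) were lower, while the list median of -0.18 lay inside the central 95% of random lists. The microglia median was -0.50 at percentile 0 with no member past the rule, and the complement genes C1qa (35.7 and 19.1 FPKM) and C1qb (28.3 and 13.98) were among its lower members.

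Antigen-presentation genes had the lowest list median, -0.91 at percentile 0, and 6 of 13 measured members were lower. The class I heavy chains H2-D1 (16.6 FPKM in B6 and 2.001 in CAST) and H2-K1 (11.3 and 2.01) were followed by H2-Aa (2.83 and 0.283), Cd74 (3.71 and 1.03), H2-T22 (8.14 and 3.36) and H2-T23 (6.97 and 2.92). B2m, the invariant light chain of class I molecules, was at 71.7 FPKM in B6 and 58.4 in CAST. Between 22.8% and 51.0% of the 31-base words of H2-K1, H2-T23, H2-D1 and H2-T22 recur in another gene, so their values are uncertain, while Cd74 and H2-Aa share 1.37% and 0.790%. The shared percent does not measure loss of CAST reads on a B6-derived reference, so all values of this list may be uncertain. When FPKM times length was summed with its near-identical gene, the difference of H2-T22 became -0.84, no longer past the rule. Interferon-stimulated genes had a median of -0.48 (percentile 0.18), with Ifit3 (5.25 and 0.738 FPKM) and Ifitm3 (10.4 and 4.40) lower among 8 measured; Ifit3 shares 61.8% of its words.

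Choroid plexus and ependyma genes had a median of -0.49 (percentile 0.01), with only Kl (4.65 and 1.65 FPKM), the klotho gene, past the rule among 13; Ttr, the transthyretin of the choroid plexus, was at 621 and 381 FPKM. Cholesterol synthesis genes had a median of -0.25 (percentile 0.01) and 1 of 20 lower, phosphomevalonate kinase Pmvk at 25.3 and 7.66 FPKM. Cytosolic ribosomal protein genes had a median of -0.33 at percentile 0, with Rps18, Rps15, Rpl37 and Rplp0 lower among 28; these 4 share from 16.6% to 49.7% of their 31-base words with other genes, and their values are uncertain. Heat shock genes (-0.22), pericyte, smooth muscle and meningeal genes (-0.23) and glutathione and detoxification genes (-0.12) also lay below the central 95%, the glutathione list with Gsta4 (31.9 and 6.93 FPKM) and Gstt1 (12.6 and 4.83) lower and Gstm7 (11.8 and 47.8) higher. Blood cell genes lay below it as well (-0.31, percentile 0.56), with Hbb-bs at 288 and 181 FPKM, Lyz2 at 8.35 and 6.40, and Hba-a2 and Hbb-bt past the rule among 8 measured. The 4 globin genes share from 54.4% to 92.6% of their words and Lyz2 shares 32.8%, so these values are uncertain; when FPKM times length was summed with the near-identical genes, the differences of Hba-a2 and Hbb-bt became -0.18 and -0.77, no longer past the rule. Glutamate receptor (0.19), postsynaptic density (0.13) and paternally expressed imprinted genes (0.14) lay above it. Pan-neuronal (-0.15), excitatory (0.13) and inhibitory neuron (-0.12), astrocyte (0.13) and endothelial (-0.05) medians were inside. Within lists near 0, some members were past the rule, among them Gabra6, a cerebellar GABA-A subunit, at 20.01 and 41.3 FPKM, Car8 of Purkinje cells at 43.7 and 17.2, Eno1 at 215 and 94.9, Gapdh at 20.97 and 7.17, Cox5b at 225 and 99.8, and Sult1a1 at 5.74 and 2.28. Eno1 is uncertain, as its copy Eno1b, which shares 89.0% of its words with other genes, went the other way (0.168 and 35.2). Shared words were not weighed for Gapdh, Cox5b and the others named here, so these differences may be uncertain too. In all, 17 of the 37 gene lists lay outside the central 95%, 5 above and 12 below.

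**Figure D1:**
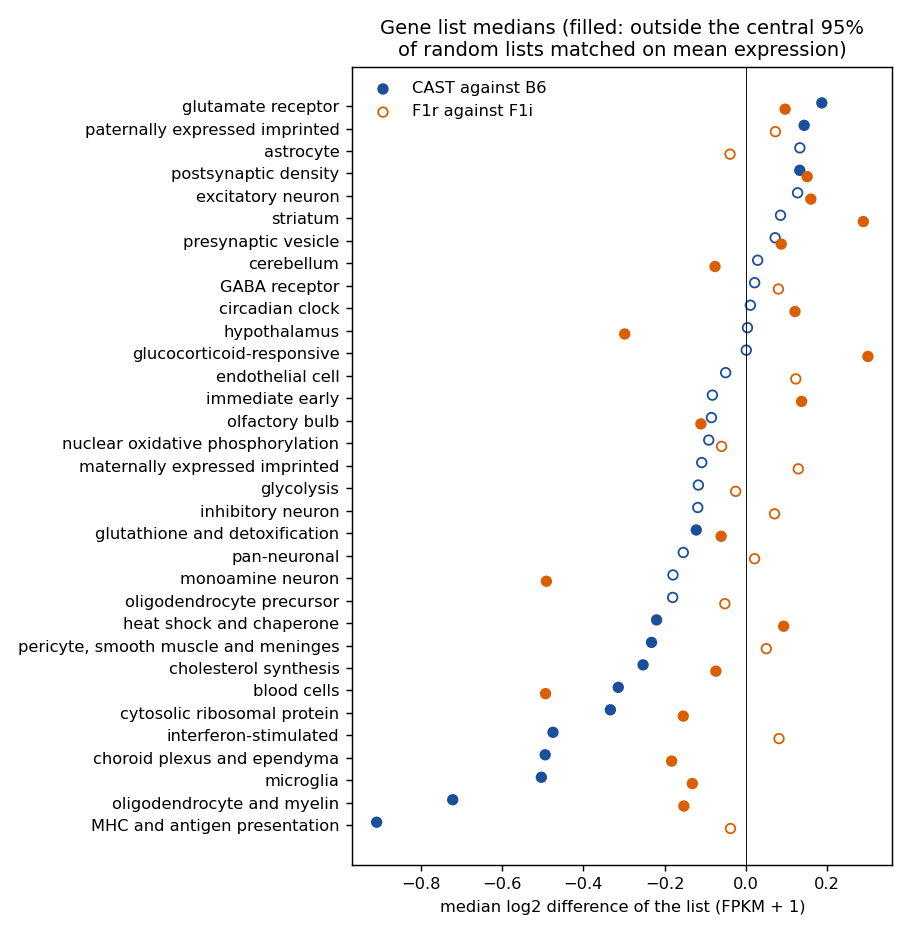
Median log2 difference of the gene lists other than the sex and strain checks, mitochondrially encoded and pituitary lists, for CAST against B6 (blue) and F1r against F1i (orange), on FPKM + 1 with 1 library per group; filled points lie outside the central 95% of matched random lists. Antigen-presentation (-0.91), myelin (-0.72) and microglia (-0.50) lists are lowest in CAST, and the striatum list is higher in F1r than in F1i (0.29).

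Among named genes, the largest single differences were mostly in genes with near-identical copies. Rps2, a ribosomal protein gene on chromosome 17 (24718116 to 24721929, GRCm38), was at 220 FPKM in B6 and 9.28 in CAST, while its processed pseudogene Rps2-ps13 on the X chromosome (52898588 to 52899469) was at 0.962 and 90.65. Rpl29 (73.1 and 0.647 FPKM), Rpl17 (59.2 and 2.55), Rpl21 (48.3 and 4.15) and the pseudogene Rpl21-ps15 (29.1 and 2.42) were lower, and Rps12-ps10 (0.320 and 67.8), Rps15-ps2 (0.163 and 43.6), Rps13-ps1 (4.21 and 134) and Rpl28-ps3 (0.946 and 48.9) were higher. The alpha-globin gene Hba-a2 was at 66.5 and 0.103 FPKM beside 107 and 137 for its neighbour Hba-a1. Hist1h4m (84.1 and 8.32) and Hist1h2ak (9.56 and 0.178) were lower, Eno1b, a copy of the enolase gene Eno1, was higher (0.168 and 35.2), and Hist1h2al was listed at 0 in B6 and at 25.9 in CAST. These genes share from 14.6% to 100% of their words with other genes and are uncertain. Rprl3, an RNase P RNA copy on chromosome 8, was listed at 0 in B6 and at 1907 in CAST. It shares 15% of its words with other genes and is uncertain too.

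Genes with little shared sequence also differed, though a low shared percent does not measure loss of CAST reads on a B6-derived reference. Fam213b, a prostaglandin F synthase gene on chromosome 4 (154895504 to 154899135), was at 70.3 FPKM in B6 and listed at 0 in CAST. The securin gene Pttg1 on chromosome 11 (43420250 to 43426251) was at 23.5 and 0.838, the paraoxonase gene Pon2 on chromosome 6 (5264147 to 5298455) at 13.4 and 0.354, and Myoc, which encodes myocilin, at 9.29 and 0.0847. In the added selection of protein-coding genes that share under 5% of their words, made after the data were seen, Usmg5, a small ATP synthase subunit (361 and 55.3), the potassium channel gene Kcng4 (9.002 and 0.445), the kallikrein Klk6 (7.16 and 0.798), matrix Gla protein Mgp (42.2 and 10.7) and Cox6a2 (8.77 and 1.79) were lower in CAST. The complex III core gene Uqcrc1 on chromosome 9 (108936633 to 108949623) was higher at 1.59 and 40.95, as were the retinol saturase Retsat (3.61 and 25.9), the ubiquitin ligase gene Rnf181 (0.460 and 12.5), Wdfy1 (3.55 and 14.5) and the ciliary gene Rsph1 (1.71 and 10.7). Of 115 named genes, 23 overlap the span of another expressed gene and their values are uncertain. For 8 of them the other gene is on the same strand, as for mt-Atp6, mt-Atp8, mt-Co3, mt-Nd4l and Tmsb15b1, and counting by strand would not part the reads; for the rest, such as Usmg5 with Taf5 and Wdfy1 with Mrpl44, the uncertainty holds to the extent that reads were counted without strand.

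The F1 libraries were set between the parents to ask whether hybrid expression was intermediate. For the 700 genes at least 2-fold apart between the strains, on a scale where B6 is 0 and CAST is 1, the median position was 0.505 in F1i (quartiles 0.405 and 0.625) and 0.493 in F1r (0.379 and 0.609). Between 0.25 and 0.75 lay 76.7% of these genes in F1i and 77.9% in F1r. The 700 genes, 213 of them processed pseudogenes, were chosen by the same parental libraries that set the scale. Parental differences made by library variation, or by reads assigned differently by allele, would also place the F1 midway. A median near the middle therefore does not by itself show intermediate expression. Rps2 was at 116 FPKM in F1i and 114 in F1r, Pttg1 at 12.6 and 10.8, Mobp at 175 and 176, H2-D1 at 10.2 and 7.23, and Uqcrc1 at 23.6 and 17.9. Every pair of a parent and an F1 library had fewer genes at least 2-fold apart than the parents did, from 169 for CAST and F1i to 248 for B6 and F1i.

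**Figure D2:**
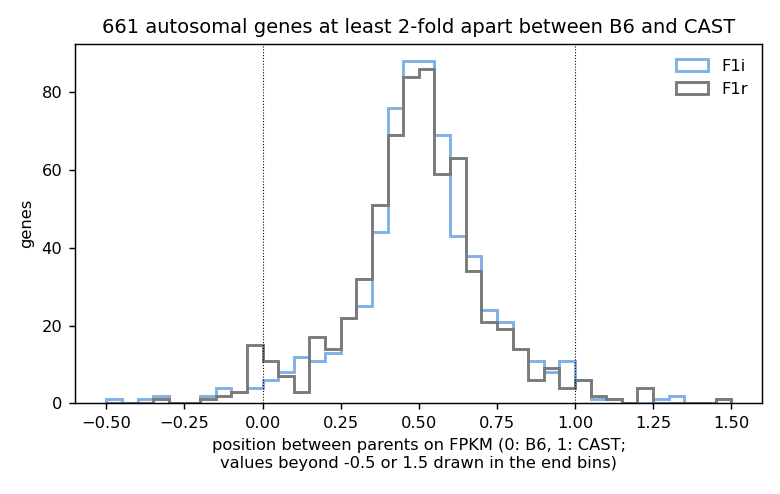
Number of autosomal genes by position between the parents on FPKM (0 is B6, 1 is CAST), for the 661 autosomal genes at least 2-fold apart between the parental libraries, in F1i (blue) and F1r (grey). Both distributions peak near the middle, with medians of 0.504 and 0.499.

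Against the mean of the parents, the mean of the F1 libraries was higher for 6 genes and lower for 15, with 1 and 10 of these protein-coding and 5 and 2 processed pseudogenes. The lower genes included Scgb1c1, a secretoglobin, at 11.1 FPKM in B6, 21.9 in CAST, 0.828 in F1i and 2.34 in F1r. The taste receptor gene Tas1r1 was at 10.03 FPKM in CAST and at no more than 0.272 in the other libraries. Bpifb4, Cyp2a5, Vmo1 and Cbr2 were likewise higher in value in CAST (4.23, 6.53, 4.63 and 4.34 FPKM) than in B6 or either hybrid, and Myoc and Coro1b were higher in value in B6 (9.29 and 17.4) than in the rest. Whether these values reflect the hybrids or differences between single pools, such as other tissue carried over, was not tested. Among named genes higher in value than the parental mean, Cacng7, Hist1h3g, Zfp969, Stk32c, Dpysl4, Rian and Dnah14 had differences from 0.81 to 0.62 and did not pass the rule. Zfp969 shares 100% of its words with other genes, Hist1h3g 60.2%, Cyp2a5 54.6%, Cbr2 14.97% and Coro1b 13.1%, and these values are uncertain. Outside the parental range by 2-fold in both hybrids were 4 genes above it (AC125531.1, Gm14391, Gm43493 and Gm9836) and 3 below it (Scgb1c1, Gm13342 and Gm24105); Gm14391 and Scgb1c1 are protein-coding and the others are processed pseudogenes or, for Gm24105, a misc_RNA. Among the lists, 16 lay outside the central 95%, with the striatum (0.13) and presynaptic vesicle (0.07) medians above it, and pericyte, smooth muscle and meningeal (-0.24), interferon-stimulated (-0.22) and myelin genes (-0.12) below it.

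The reciprocal hybrids carry the same autosomal genotypes, and F1r against F1i asked what the direction of the cross changed, together with all variation between libraries. Among named genes, mitochondrially encoded ones held the largest differences; of 20 unprocessed pseudogenes, 8 were lower and 1 higher in F1r, and Gm13341 on chromosome 2, singled out after its value was seen, was at 1.56 FPKM in F1r and 2087 in F1i, beside 1.41 in B6 and 2241 in CAST, and is uncertain with 47.98% of its words shared. Among all 13750 genes 32 were higher and 36 lower in F1r, and 18 and 11 of these were protein-coding. In F1r, mt-Nd3 was at 9.70 FPKM against 1254 in F1i, mt-Co3 at 20.8 against 1693, mt-Atp6 at 3.43 against 179 and mt-Co2 at 25.1 against 989. These encode subunits of complex I, cytochrome oxidase and ATP synthase. In the opposite direction mt-Nd1 was at 1914 in F1r and 455 in F1i, mt-Cytb at 1711 and 566, mt-Nd2 at 431 and 146, and mt-Co1 at 6657 and 2931. In each of these 8 mitochondrial genes F1r lay near B6 and F1i near CAST: mt-Nd1, for example, was at 1853 in B6 and 563 in CAST, and mt-Co2 at 24.8 and 1025. The 31-base words of mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3 recur at 98.1% or more in other annotated genes, so their levels are uncertain. The level of mt-Co1, which shares 63.9%, is uncertain too. Its CAST minus B6 difference of -1.13 became -0.08 when FPKM times length was summed with its near-identical genes. By contrast, mt-Nd1 (mitochondrial positions 2751 to 3707) shares 0% and mt-Cytb 6.55%. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 were alike in the 4 libraries, at 7741 to 8102 and 31991 to 35164 FPKM.

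**Figure D3:**
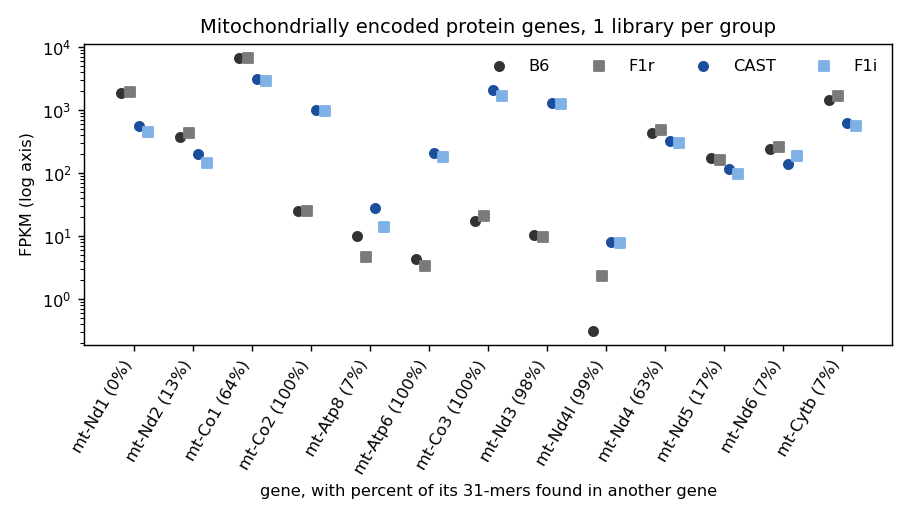
FPKM (log axis) of the 13 mitochondrially encoded protein genes in B6, F1r, CAST and F1i, 1 library each, with the percent of each gene's 31-base words found in another gene. For mt-Nd1, F1r lies close to B6 (1914 and 1853) and F1i close to CAST (455 and 563), whereas mt-Atp8 (9.97 in B6, 4.69 in F1r, 28.02 in CAST and 14.2 in F1i), mt-Nd4l and mt-Nd6 depart from that arrangement.

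Across genes, which are not independent replicates, the slope of the F1r minus F1i difference on the CAST minus B6 difference was -0.9997 over the 13 mitochondrially encoded genes (standard error over genes 0.04). This fit rests largely on mt-Co2, mt-Atp6, mt-Co3 and mt-Nd3, which had the largest parental differences (5.31 to 6.84). They share 98.1% or more of their words and are uncertain. The slope was -0.14 over 484 X-linked genes and -0.03 over 13239 autosomal genes, with single autosomes from -0.32 (chromosome 2) to 0.08. Restricted to protein-coding genes, it was -0.41 on the X chromosome against 0.01 to 0.15 on single autosomes. Among those that share under 5% of their words, it was -0.15 against 0.01 to 0.12. On chromosome 2 the slope was 0.08 among protein-coding genes, and the Spearman correlation over all its genes was 0.19. The slope of -0.32 is therefore not a general trend of that chromosome. Firre, an X-linked long non-coding RNA (50555744 to 50635321), was at 10.9 FPKM in B6, 2.66 in CAST, 2.69 in F1i and 14.1 in F1r. Tmsb15b1, an X-linked thymosin gene with 65.8% shared words, was at 5.96 in B6, 3.99 in F1r and listed at 0 in CAST and F1i. Maternally and paternally expressed imprinted lists had slopes of -0.12 (10 genes) and 0.17 (21 genes).

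**Figure D4:**
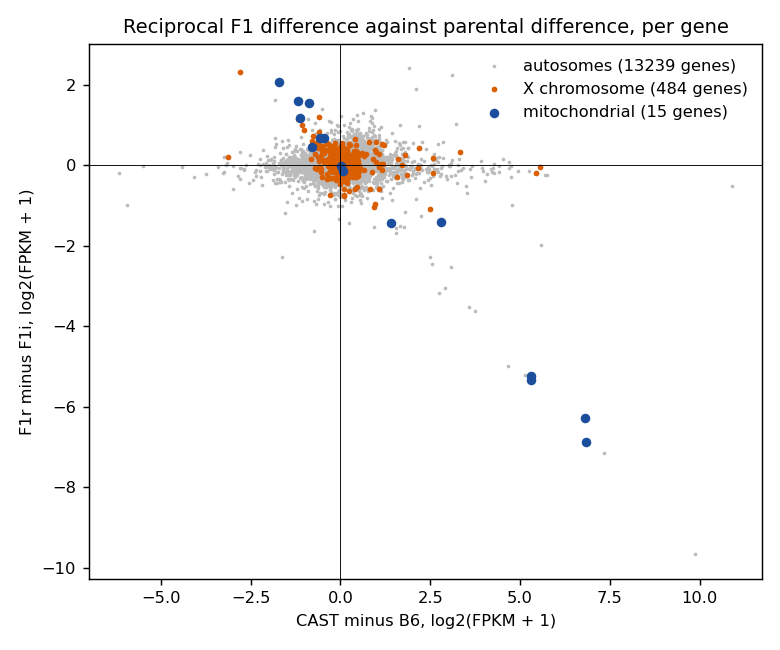
Log2 difference (FPKM + 1) of F1r minus F1i against CAST minus B6 for each of 13239 autosomal (grey), 484 X-linked (orange) and 15 mitochondrial (blue) genes. Mitochondrial genes lie along a line of slope -0.99, and most autosomal genes lie near 0 on the vertical axis.

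Between the hybrids, lists of regional genes had medians outside the central 95%, with 1 of 10 monoamine neuron, 0 of 10 hypothalamus and 0 of 14 striatum genes past the 2-fold rule. Monoamine neuron genes had a median of -0.49, below all random lists, with the serotonin transporter Slc6a4 (2.29 FPKM in F1i and 0.634 in F1r) past the rule; the serotonin-synthesis gene Tph2 was at 3.55 and 1.43 and the dopamine transporter Slc6a3 at 4.31 and 2.77. The hypothalamus median was -0.30 at percentile 0, with the oxytocin gene Oxt at 30.4 and 16.6. All 14 striatum genes were higher in value in F1r, with a median of 0.29 above all random lists, as in Gng7 (21.2 and 28.8). Blood cell genes had a median of -0.49, made of lower haemoglobin values such as Hbb-bs (287 and 184) while the neutrophil genes S100a8 (1.80 and 5.59) and S100a9 (2.76 and 6.80) were higher. Choroid plexus and ependyma (-0.18), myelin (-0.15), microglia (-0.13) and cytosolic ribosomal protein (-0.15) medians lay below the central 95%, and excitatory neuron (0.16) and postsynaptic density (0.15) medians above it. Of the gene types, singled out after the data were seen, the 192 genes annotated as to be experimentally checked (TEC) had a median of 0.43 and the 14 sense_intronic genes one of 0.31, and in CAST against B6 these were 0.39 and 0.43. In total 23 of the 37 lists lay outside it, 11 above and 12 below. Other named genes past the rule were Cox20 (1.89 and 12.7), which overlaps Hnrnpu on the other strand, Ppp2r3d (0.261 and 2.92), the growth hormone gene Gh (0.151 and 3.29), mt-Atp8 (14.2 and 4.69) and mt-Nd4l (7.92 and 2.37), and the pseudogenes Rps4x-ps (9.23 and 1.11) and Apoo-ps (7.196 and 1.80), which share 75.7% and 100% of their words.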

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

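The tests on the parent written second, on exchanged libraries, on mitochondrial copies and on read loss in protein-coding genes were chosen after the result was seen; those on shared reads, on whole families and on brainstem genes were chosen after the pattern was seen but before their own values were.

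Transcripts under 200 bases, left out of every comparison, held 68.9% of the total FPKM in B6, 64.9% in CAST, 69.7% in F1i and 66.5% in F1r. The Y RNA Rny3 alone, 102 bases long, was at 511151 FPKM in B6 and 486506 in CAST, and Rny1 at 171574 and 94492.

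Mitochondrially encoded RNA of each F1 library resembled the parent written second in its label, with median positions over 9 genes of 0.966 in F1i and -0.00047 in F1r. The 28 X-linked genes at least 2-fold apart between the parents, most of them pseudogenes, lay midway (0.479 and 0.480). The 6 protein-coding ones among them lay at 0.963 and 0.307. Xist near 0 and Ddx3y expressed in every library point to male pools. RNA read only from a single X chromosome would then not lie midway in both hybrids. The X-linked pseudogene Rps2-ps13 did, at 53.7 FPKM in F1i and 51.9 in F1r, and shares 94.5% of its words. The midway values are therefore uncertain as levels of the X-linked loci. Against inheritance of the X chromosome from the parent written first, the slope over all X-linked genes was -0.135, below the highest autosomal slope of 0.08; against the mother being written first, the slope over paternally expressed imprinted genes was 0.167, above the lowest autosomal slope of -0.32, although among protein-coding genes it was -0.01 against 0.01 and so undecided, and that over maternally expressed genes (-0.12, standard error over genes 0.36) was too imprecise to count. As the whole cause of the joint pattern, reads shared with nuclear copies of mitochondrial DNA are argued against by X-linked protein-coding genes with under 5% shared words. Their slope was -0.152 (standard error over genes 0.04) against 0.01 to 0.12 on single autosomes. That slope does not bear on the mitochondrial values themselves. Of the mitochondrially encoded list only mt-Nd1 shares under 5% of its words. It was at 1853 FPKM in B6, 563 in CAST, 455 in F1i and 1914 in F1r. A candidate explanation is that the parent written second was the dam of male pools. For it, the slope over protein-coding X-linked genes was -0.4097, below the 0.01 to 0.15 of single autosomes. The slope was far from the -1 of full single-parent expression. Library variation in the parental difference also pulls such a slope toward 0, so this distance decides nothing. An exchange of the F1i and F1r libraries after a cross written dam first predicts the same values, including the F1i mitochondrial position of 0.9655. It cannot be told apart from the parent written second being the dam, as the labels do not name the dam.

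Among genes at least 2-fold apart, more processed pseudogenes were higher than lower in CAST against B6 (195 and 18 of 644) and more protein-coding genes were lower than higher (225 and 133 of 12300). Reads shared with near-identical copies may account for part of this: 10.2% of protein-coding genes with at least 50% shared words were lower in CAST against 1.02% of those with under 5%, a ratio of 9.999. Higher in CAST were 13.2% against 0.613%, so calls were more frequent in both directions. The ratio therefore does not explain why more protein-coding genes were lower. With at least 50% shared words, 44 were higher and 34 lower. From 5% to under 50% these were 25 and 85, and under 5% they were 63 and 105. For 33 lower genes with a copy, the median of -1.496 became -0.3672 when FPKM times length was summed over the family. This met the bound of -0.5 set beforehand against a change of whole families, but by less than its spread (quartiles -1.25 and -0.08), and 10 of these genes, some from the same family, still had sums at least 2-fold lower, so such a change stays open. Loss of CAST reads on a B6-derived reference stays open: after median-ratio scaling, the 0.897 lower genes per higher gene over all types met the bound set beforehand against it, but pseudogenes carry that ratio, which after the same scaling was 2.03 over protein-coding genes and 2.302 over those with under 5% shared words, where truly lower expression would give the same. Differences between the strains themselves, such as a lower amount of myelin RNA in CAST, remain among the open explanations and were not tested apart from these.

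In F1r against F1i the monoamine list had a median of -0.49, with 1 of 10 genes past the 2-fold rule, and the striatum list a median of 0.29, with 0 of 14 past it. Uneven dissection or other tissue could produce this, and its test asked for a regional or blood list at 0.5 or more in size. The pituitary list met that value literally at 0.8157, but it holds 2 measured genes that go opposite ways (Gh 1.90, Pomc -0.26). A minimum of 3 members was required only after this was seen. The blood cell list came just short, with a median of -0.49 at percentile 0, although 2 of its 8 measured genes were higher past the rule and 0 lower. The test is read as undecided. For uneven sampling of brainstem and striatum, an added list of 28 brainstem genes was used, 27 of them measured at a mean FPKM of at least 0.1. It had a median of -0.251 at percentile 0.05, in the predicted direction but short of the bound of -0.3 set beforehand. This list was computed on FPKM + 0.1, so its median is not on the scale of the other list medians. Most of these genes were under 1.5 FPKM; the more abundant Glra1 was at 6.99 FPKM in F1i and 5.49 in F1r, and Spp1 at 19.96 and 17.9. Sampling therefore cannot be told apart from an effect of the cross direction, which with 1 pool per cross was not tested. A shift in RNA composition or quality between the libraries stays open too and had no test of its own: TEC and sense_intronic genes had medians of 0.43 and 0.31 in F1r against F1i, and in CAST against B6, where these were 0.39 and 0.43, the striatum (0.09) and monoamine (-0.18) medians lay inside the central 95% of random lists.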

How the results depend on the processing

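The settings of protein-coding genes alone, under 5% shared words, and list medians after rescaling were chosen after the data were seen. Of 131 repeats of the summary results, 67 stayed within 1.5 times a count or within the spread of a value. Of 333 repeats of list medians, 315 kept their place inside or outside the central range of random lists, 5 became stronger, 11 weaker and 2 reversed. Of 362 repeats of named genes, 334 kept their call by the 2-fold rule, 24 became stronger and 4 weaker. Direction was compared only for lists outside that range and genes past the rule. Other medians and genes may have changed direction. The cause was not tested except where a setting takes in fewer or more genes. No paired analysis was possible because each group has 1 library and no result comes from a test. The confidence-interval rule was not run.

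With a pseudocount of 0.1, 571 genes were higher and 492 lower in CAST, and 111 higher and 72 lower in F1r against F1i. In F1 against the parental mean 20 were higher and 27 lower, and the autosomal slope was -0.0153. With no filter on low values, 56 genes were higher in F1r, 26 lower in F1 against the parents, and the slope was -0.0186. At a mean FPKM of at least 5, with fewer genes, the counts were 212 and 156 for CAST, 11 and 21 for F1r, 1 and 6 for F1 against the parents, and 1 gene each above and below the parental range; slopes were -0.0655 on autosomes and -0.0884 on the X chromosome.

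Rescaling to a common total took in all transcripts, including those under 200 bases, and left 11965 genes past the filter. It also made values smaller against the added 1, so its counts do not reflect scaling alone. It gave 100 genes lower in CAST, all among the main 310, 19 higher and 22 lower in F1r, and 1 higher in F1 against the parents. There was 1 gene each above and below the parental range, with positions of 0.3938 in F1i and 0.46 in F1r, and an autosomal slope of -0.051. The median of all genes moved to 0.32 for CAST against B6 and 0.25 for F1r against F1i. Less that median, the pituitary list in F1r against F1i reversed to -0.2987 and the mitochondrially encoded list in F1 against the parents to 0.0482.

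Single transcripts gave more calls, 1117 and 1083 for CAST, 320 and 356 for F1r, 89 and 188 for F1 against the parents, and 25 above and 24 below the parental range; positions were 0.4541 and 0.457, and slopes 0.017 on autosomes, a reversal, -0.3479 on the X chromosome and 0.579 for paternally expressed genes. Protein-coding genes alone gave 133 higher in CAST, 18 and 11 in F1r, 1 higher in F1 against the parents, 1 each above and below the range, a position of 0.5209 in F1r, and slopes of 0.074 on autosomes, reversed, and -0.4097 on the X chromosome. Genes with under 5% shared words gave 83 and 145 for CAST, 14 and 3 for F1r, 1 and 5 for F1 against the parents, 1 each above and below the range, a position of 0.5195 in F1r, and slopes of 0.1006 on autosomes, reversed, -0.2161 on the X chromosome and -1.2156 over 3 mitochondrial genes. On the log2 scale positions were 0.5284 and 0.5207. The rule with the 99th percentile kept 389 genes higher and 308 lower in CAST. Only 68 of 13750 genes were at least 2-fold apart between F1r and F1i, so this added condition could remove few genes. Estimated depth was lowest in CAST and F1r, at 0.714 and 0.726 of B6, and its effect on low genes was not tested.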

Other observations

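Glucocorticoid-responsive genes had a median of 0.30 in F1r against F1i, above all random lists, with none of 15 past the 2-fold rule. Sgk1, a kinase induced by glucocorticoids, was at 42.0 FPKM in F1i and 66.0 in F1r, Tsc22d3 at 71.7 and 98.5, and Ddit4 at 24.6 and 36.8, while B6 held 74.3, 84.6 and 39.8 and CAST 47.0, 71.1 and 23.8. Immediate early genes (0.14), circadian clock genes (0.12) and heat shock genes (0.09) also lay above the central 95% in F1r, and cerebellum (-0.08) and olfactory bulb genes (-0.11) below it. The GABA receptor (0.08), maternally expressed (0.13) and paternally expressed imprinted (0.07), glycolysis (-0.03) and nuclear oxidative phosphorylation (-0.06) medians lay inside it.

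The values that follow were singled out after the data were seen. Across 13239 autosomal genes, which are not independent replicates, the Spearman correlation of the reciprocal with the parental difference was 0.21, while the slope was -0.03. The gene Gm14391 was at 0.672 FPKM in B6, 2.53 in CAST, 14.7 in F1i and 25.3 in F1r. The short transcript Gm26202, of 65 bases, was at 10163 FPKM in F1i and between 57953 and 68168 in the other libraries.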
